A study of Mus musculus with 6 samples.

How the data were processed

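The 6 libraries are single-nucleus ATAC-seq of mouse gastrocnemius, 3 from normal muscle and 3 from muscle 2 weeks after sciatic nerve section, made with the 10x Genomics single-cell ATAC v1 chemistry per the labels. For each library the authors deposited a list of nucleus barcodes, a list of peaks without scores and a sparse matrix of raw counts, whose unit is the count of transposase cut ends per peak and nucleus, not normalised. Per the submitters' processing notes the tools were Cell Ranger and STAR, without versions, and the genome build mm10; per the file headers the matrices were written by software version 1.1.0. Between 87.3 and 90.2% of the values in a matrix were even, as when both ends of a fragment are counted, so counts are not independent and intervals cover counting error only. Peaks had been called per library, and each matrix holds counts only inside its own peaks. All peak ends lay within the GRCm38.p6 chromosomes of the GENCODE vM21 annotation used for genes.

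Peaks of the 6 libraries on chromosomes 1 to 19, X and Y were merged where they overlapped by 1 bp. Regions in which every library had a peak were called shared, and counts in peaks were summed per region, library and class of nuclei. The shared regions held 95.6 to 96.6% of the counts of a normal and 84.6 to 90.0% of those of a denervated library. A promoter is the sum of the shared regions within 1 kb of any annotated start of a protein-coding gene, so that neighbouring genes such as Myf5 and Myf6, or Cmtm1 and a predicted gene, can share a region. Regions are counted whole, so a promoter can reach far beyond 1 kb: the region over the Mylk4 start is 57113 bp wide. Coordinates printed for a promoter are those of its gene, and those printed for a region are its own. For each region or promoter counts were tested with edgeR's quasi-likelihood test on TMM-scaled library sums after its low count filter, with Benjamini-Hochberg adjustment and a threshold of 0.05; the library is the replicate throughout. Log2 changes are denervated over normal and carry their standard error. CPM of tested regions and promoters are counts scaled to the library total times its TMM factor, and carry the standard deviation between libraries. Other CPM, such as those of peaks and start regions, carry no TMM factor. "Rose" and "fell" are used for tests past the threshold.

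Nuclei with at least 1000 counts in shared regions (32986 of 36285) were reduced by latent semantic indexing (30 components, 29 kept), joined to 20 nearest neighbours and grouped by Leiden clustering at resolution 1, which gave 32 clusters. A cluster took the class of a fixed marker list when at least 0.5 of the list's informative genes reached 0.5 of the level in the highest cluster, with a lead of 0.1 over the next list, and less than 30% of its nuclei resembled simulated doublets. The naming rule was settled after 5 scorings had been looked at, and its limits were loosened in part because earlier ones left clusters with muscle genes unnamed; the last 2 scorings were carried into values. Names end in -like, since they rest on accessibility alone. Shares of nuclei per class were compared with a two-sided exact permutation test of the difference of means, with Benjamini-Hochberg adjustment over classes, as were the peaks, covered length, nuclei and counts per nucleus of each library. Classes with at least 50 nuclei in every library were tested for regions.

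Fixed lists of genes for pathways and cell types were tested at promoters with camera (preset correlation 0.01) when at least 3 members were measured, with an estimated correlation and fry beside it. Motifs were fixed consensus sequences searched on both strands within 250 bp of region centres, compared by a Cochran-Mantel-Haenszel odds ratio in strata of GC decile. The 8 largest rises and 8 largest falls among promoters, and 5 and 5 among regions (3 and 3 in other classes), are the candidates for naming, when past the threshold with all 3 libraries of a group beyond those of the other and not a predicted gene. From each list up to 4 members with the smallest p may be named, and Myh4, Myh1, Myh2, Myh7, Chrna1, Chrng, Myog, Runx1, Trim63 and Fbxo32 are always given. Genes in the plot of promoters were picked from these partly after their values were seen, and Mymk, Ankrd1 and Igfn1 are named for the unnamed cluster after the fact. The groups, tests, lists, motifs, naming of genes and the first set of settings listed next were chosen before the data were examined.

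Other settings chosen then were DESeq2 and its size factors, no low count filter, a replicate block, leaving out each library, regions in at least 3 libraries, at least 0.5 of the merged length called, peaks of at least 5 CPM, nuclei with a count in place of counts, loess offsets against abundance or GC, an offset of the called length, starts within 250 bp, gene activity (gene body and 2 kb upstream), and other clusterings, doublet, depth and motif settings. Chosen after seeing the data were filling the uncalled length of a region at the 10th percentile of the library's own count density, library size without TMM, the earlier naming rule, a batch term for the replicate 3 libraries and replicates 1 and 2 alone. The length offset divides by the called length and so removes real gains in which peaks widen, and lowers promoters at large, so lists under it are compared with the median of all promoters. The fill leaves that median near 0 (0.0039). It is not always the milder setting: it shrank most of the largest whole-muscle region changes further than the offset did, as near Ino80c (0.85 against 1.77). Totals of alternatives for promoters and motifs cover all named genes and all motif tests. Reversals are named 1 by 1 only for a subset of the genes, chosen after a first, fuller table had shown many more of them: the always given genes, the largest changes, and members past the threshold in the atrophy and myogenic lists and the lists that pass camera.

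On simulated data made from the fitted means and spreads, some features were raised or lowered by a known fold. In whole muscle the edgeR test found 83.6% of promoters changed 1.5-fold, 91.0% of those changed 2-fold and 98.5% of those changed 4-fold, and 15 of 197 calls (7.61%) were false. For whole-muscle regions it found 2.99%, 28.4% and 80.3%, with 9 of 83 calls false. In myonuclei-like nuclei it found 79.1%, 92.5% and 98.5% of promoters (12 of 192 calls false) and 0%, 25.4% and 79.4% of regions (4 of 71). Of regions changed 1.5-, 2- and 4-fold it found 4.76, 26.3 and 91.4% in endothelial-like (3 of 74 calls false) and 3.08, 32.8 and 71.2% in progenitor-like nuclei (3 of 74). It found 7.94, 41.0 and 88.3% in macrophage-like (11 of 94, 11.7%), 0, 14.1 and 79.6% in satellite cell-like (3 of 55) and 1.64, 23.3 and 89.5% in tenocyte-like nuclei (10 of 76, 13.2%). Few features were changed (67, 67 and 66 promoters in whole muscle), far fewer than were called there in the data. Differences in called length were not simulated. These rates therefore need not hold for the real tests. Camera found the raised list and passed 0 of 25 unchanged ones. Genes were simulated independently there, so how camera behaves with correlation within lists was not tested. Simulated motif odds ratios of 1, 1.5 and 2 came back as 0.993, 1.48 and 2.01. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.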

Results

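Chromatin accessibility was measured nucleus by nucleus in mouse gastrocnemius, a calf muscle, with single-nucleus ATAC-seq, in which a transposase cuts and tags open DNA and droplet barcodes keep the nuclei apart. The labels give 3 libraries from normal muscle and 3 from muscle taken 2 weeks after a piece of the left sciatic nerve had been removed, all from male 12-week-old C57BL/6J mice. They do not state whether each library came from its own animal, so the p-values measure the spread between these libraries, which can be technical. The normal libraries held 7527, 7975 and 4742 nuclei with 76791224, 85073639 and 80228989 counts in peaks. The denervated libraries held 6428, 6471 and 3142 nuclei with 103354335, 92031347 and 82953842. Neither the number of nuclei (6748 ± 1752 against 5347 ± 1910, mean ± SD, n = 3 per group) nor the median count per nucleus (10359 ± 4590 against 14693 ± 7560) differed beyond the spread between libraries (two-sided exact permutation p = 0.5 for each).

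The first comparison asks whether more peaks were called in denervated than in normal muscle. Every denervated library had more than any normal library: 131211, 121274 and 104716 peaks were called in the denervated libraries and 81639, 88632 and 82257 in the normal ones. Within each group the number of peaks rose with the counts in peaks, so peak number alone does not separate open sites from depth. Genes of the neuromuscular synapse, of slow and embryonic muscle and of macrophages were among those with a region near a gene start called in the denervated libraries alone. Some lay beside start regions called in all libraries, and some, as at every macrophage gene, held few counts. No listed gene had one in the normal libraries alone. The mean number of peaks was 119067 ± 13385 against 84176 ± 3871 (SD, n = 3), and the covered length was 111 ± 12.7 Mb against 85.3 ± 5.92 Mb. Both differences gave an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow (0.2 after adjustment over the 4 measures per library). With peaks of at least 5 CPM (counts scaled to a common library total) the means were 44865 against 37546 peaks (exact permutation p = 0.1) and 79.9 against 67.9 Mb, and the covered lengths overlapped (74.8 Mb in normal 3, 73.8 in denervated 3; exact permutation p = 0.2). The mean count per kb of peak was 836 ± 24.7 in the denervated and 948 ± 75.0 in the normal libraries.

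Merging the peaks gave 144829 regions, of which 58958 were called in all 6 libraries (median length 1178 bp). Another 20706 regions were called in all 3 denervated libraries and in no normal one, and 2748 showed the opposite. Few of either kind lay within 1 kb of a gene start, 2.43% and 1.71% against 21.9% of the shared regions. Promoter regions seen only after denervation belonged to 494 protein-coding genes, and those seen only in normal muscle to 49. Among the synaptic genes they were those of Chrng, the fetal acetylcholine receptor subunit, and Colq; among slow contractile genes those of Myh7b, Tnnt1, Tnni1 and Csrp3; among embryonic contractile genes those of Myh3, Tnnt2 and Myl4. The Colq region held 135, 146 and 3 counts, and its start regions shared by all libraries stood at 16.8 and 16.9 CPM (normal, denervated) and at 14.9 and 8.22. Shared start regions also existed for Myl4 (45.2 and 44.2), Tnnt1 (4.21 and 12.0), Atf3 (81.3 and 80.2), Fgfr1, Egfl7, Gdf5 and Pi16. CPM of start regions here are scaled to all counts in peaks. They do not compare with CPM of tested promoters below, which are scaled to promoter counts and TMM factors. The region over the start of Chrng (chromosome 1, 87197135 to 87208294, GRCm38) held 58.6 ± 9.40 CPM in the denervated libraries and was not called in normal muscle. Of the macrophage markers Adgre1, Csf1r, Mrc1, Fcgr3 and F13a1 had such regions, of the endothelial markers Pecam1 and Egfl7, of the fibro-adipogenic progenitor markers Pi16, of the tenocyte markers Fmod, and of the signalling and early response genes Gdf5, Atf3 and Fgfr1. The macrophage regions stood at only 1.68 to 2.54 CPM, Pecam1 at 1.41, Myh7b at 1.30 and Myh3 at 2.55. The 10th percentile of called regions in the normal libraries was 0.997 to 1.24. Csrp3 (11.9), Tnnt1 (12.0), Tnnt2 (6.22), Myl4 (5.82) and Atf3 (14.0) stood higher. The Fgfr1 region held 220, 134 and 8 counts. Over the gene bodies of the 20 myonuclei markers the order was the other way round, with 27 regions called only in normal and 1 only in denervated muscle. A call depends on depth, and with peaks of at least 5 CPM alone the region counts were 7461 and 2628.

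Promoters of protein-coding genes over all nuclei were compared to ask which genes gained and which lost accessibility on denervation. In the main fit most listed genes of fast contraction, glycolysis and mitochondria and 5 of 9 of polyamine metabolism lost counts at their promoters. The acetylcholine receptor subunits Chrna1 and Chrnd, the myogenic regulators Myog and Runx1 and several genes of the embryonic and slow contractile lists gained them. With an offset for called length, which lowers promoters at large, Chrnd, Tnnt1, Myoz2 and Tpm3 lost the call and Myog and Runx1 turned to falls. The E3 ligase genes usually read as markers of atrophy did not gain: the Trim63 promoter fell and that of Fbxo32 did not change detectably. Of 13568 promoters tested, 2633 rose and 2345 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and in 7070 (52.1%) the groups did not overlap, which chance gives for 10%. The balance rests on the scaling: library size alone gave 5355 rises and 1080 falls (median of all promoters 0.17), and the length offset 551 and 3669 (median -0.17).

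The promoters with the largest rises were those of Slc6a15, Eppk1, Ankrd1, Chrna1, Aqp1, Gng4, Scnn1a and Fzd10, with log2 changes from 4.95 to 3.46. At Ankrd1 (chromosome 19, 36111961 to 36120099) CPM went from 7.77 ± 2.17 to 164 ± 16.7 (SD, n = 3), a log2 change of 4.40 ± 0.19 (SE; edgeR adjusted p = 1.23e-05). At Chrna1 (chromosome 2, 73563215 to 73580338) they went from 4.85 ± 2.18 to 66.6 ± 5.39, a log2 change of 3.77 ± 0.26 (adjusted p = 4.93e-05). Counts exist only inside each library's own peaks, so these folds join longer called stretches to more counts per base. The length called at the Chrna1 promoter was 461 bp on average in normal and 4484 bp in denervated libraries. With the uncalled length filled at a low background the change was 0.93 at Chrna1, 0.65 at Ankrd1 and 1.36 at Aqp1, while Slc6a15 (0.18) and Gng4 (-0.04) no longer passed. With the length offset Ankrd1 (0.06), Gng4 (0.13) and Fzd10 (0.29) did not pass. The largest falls were at Mylk4, Slc2a2, Cmtm1, Smco1, Odf3l2, Rims4, Asb11 and Smox, from -3.62 to -2.70, and each stayed past the threshold with the uncalled length filled. Mylk4 (chromosome 13, 32700834 to 32783954) went from 1531 ± 318 to 125 ± 40.5 CPM, and Smox, which oxidises spermine, from 874 ± 308 to 135 ± 15.2.

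Among the genes given whatever their result, Myh4, the fastest myosin heavy chain (chromosome 11, 67238029 to 67260446), fell from 2065 ± 238 to 379 ± 83.7 CPM (log2 -2.45 ± 0.18, adjusted p = 6.65e-05) and Myh1 fell by 1.48. Myog rose by 1.20 ± 0.09 (46.8 ± 0.82 to 108 ± 14.5) and Runx1 by 1.19 ± 0.06 (77.3 ± 1.42 to 177 ± 10.6); with the offset for called length they stood at -0.30 and -0.25, below the median of all promoters (-0.17). Trim63 fell by 0.90 ± 0.26 (adjusted p = 0.0278), a call lost when any library except normal 3 was left out (log2 -0.65 to -1.01 then). Fbxo32 stood at 968 ± 205 and 910 ± 153 (log2 -0.09, adjusted p = 0.723). The regions counted here were wide: 67213758 to 67272791 for Myh4, 134313654 to 134334544 for Trim63 (chromosome 4) and 58170247 to 58216864 for Fbxo32 (chromosome 15). Their values thus do not describe the gene start alone. Myh2, Myh7 and Chrng had no promoter region shared by all 6 libraries and were not tested.

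**Figure D1:**
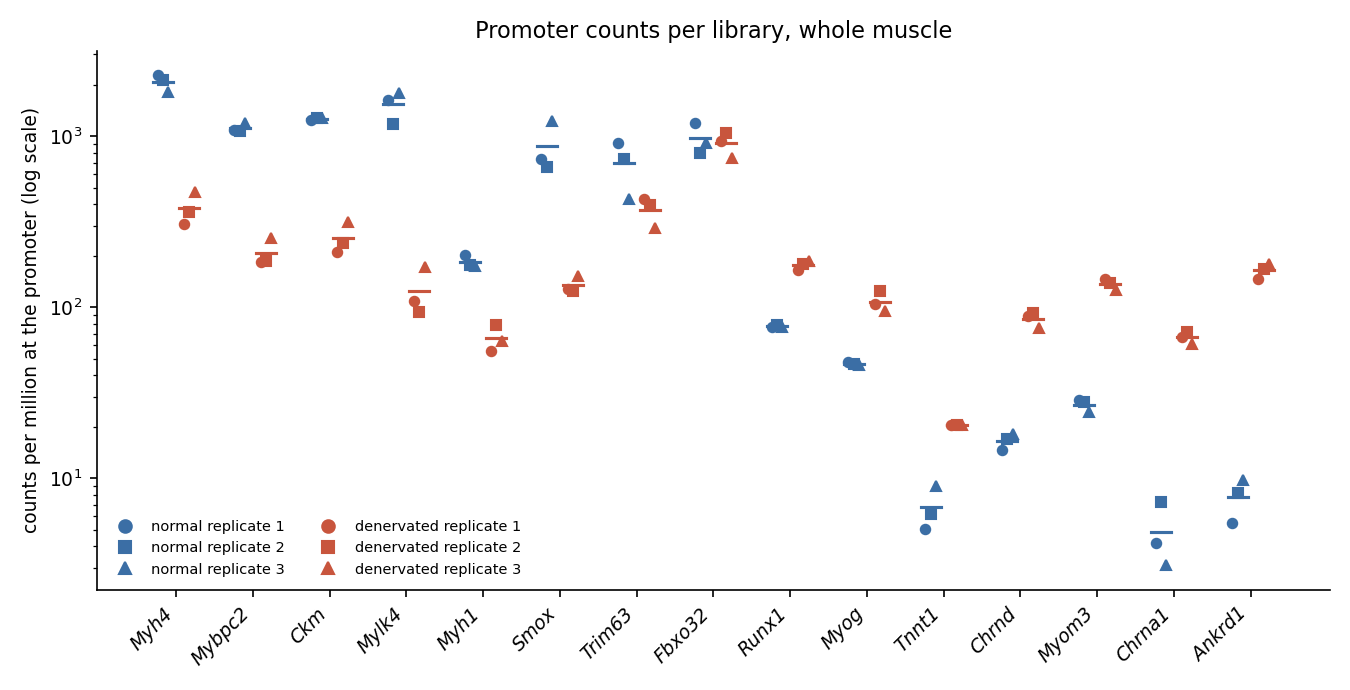
CPM at 15 promoters in the 3 normal and 3 denervated libraries, on a logarithmic axis; each point is a library and each line a group mean. Points of the groups separate for Myh4, Mylk4 and Ckm, higher in normal muscle, and for Ankrd1, Chrna1 and Chrnd, higher in denervated muscle (Ankrd1 and Chrnd not past the threshold with an offset for called length, at 0.06 and -0.13), and overlap for Fbxo32.

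Fixed gene lists were compared with all other promoters by camera, with Benjamini-Hochberg adjustment over 26 lists and a preset correlation; with a correlation estimated from the data 0 lists passed, here and below. Of the fast contractile and glycolytic genes 22 of 24 fell over all genes tested and 23 adjusted over the list alone (median log2 -1.20, camera adjusted p = 8.71e-28). Mybpc2 (-2.42), Gpd1 (-1.13) and Phkg1 (-1.44) led beside Myh4. Of the mitochondrial and fatty acid oxidation genes 26 of 32 fell (28 adjusted over the list alone; median -0.37, adjusted p = 5.29e-12), among them Perm1 (-1.98), Ckmt2 (-1.54), Slc25a4 (-1.51) and Ucp3 (-1.40). Of the myonuclei markers 19 of 20 fell, also adjusted over the list alone (median -1.19, adjusted p = 3.77e-24), with Ckm at -2.32 and Tnni2 at -1.29; 11 of these genes are in the fast contractile list too. Of the polyamine genes 5 of 9 fell (6 adjusted over the list alone; adjusted p = 0.000157), namely Amd1 (-1.69, 0.0024 with an offset for called length), Smox, Sms (-0.55), Sat1 (-0.27) and Odc1 (-0.60, named after its value was seen). Relative to all promoters the medians of these 4 lists stayed lower under every scaling tried. With the length offset the distance shrank from -0.37 to -0.09 for the mitochondrial and from -0.27 to -0.04 for the polyamine list. Of the 32 mitochondrial genes 15 fell with library size alone and 16 with the length offset, and of the 9 polyamine genes 4 and 3.

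Of the acetylcholine receptor and synaptic genes 7 of 17 rose and 4 fell (7 and 7 adjusted over the list alone), and camera gave an adjusted p of 0.000952 towards higher. The rises at Chrna1, Chrnd (2.37) and Ncam1 (1.71) were large, the mean was 0.55 and the median -0.02, so the median and the test differed in sign; with the offset for called length, which lowers promoters at large, 3 rose and 7 fell. Of the list of embryonic and perinatal contractile genes 3 of 6 rose, counted either way (camera adjusted p = 2.64e-08). They were Ankrd1, which is in the myotendinous list too, Myom3 (2.34) and Mybph (0.54, or 0.49 and not past the threshold without denervated 2). The list's mean was 1.29 and its median 0.48. The embryonic myosin gene Myh3 had no shared promoter region and was not tested. Of the slow contractile genes 5 of 8 rose, counted either way (adjusted p = 0.0137), with Myoz2 at 1.93, Tnnt1 at 1.60, Tpm3 at 0.75 and Atp2a2 at 0.40. The call was lost with the uncalled length filled and with counts over the gene body, and with the offset for called length the median no longer stood above all promoters (distance 0.58 before and -0.0032 after). Of the extracellular matrix genes 12 of 20 rose (14 adjusted over the list alone; adjusted p = 0.000157), among them Lox (1.40), Ccn2 (0.92), Sparc (0.84) and Thbs1 (0.80). Of the fibro-adipogenic progenitor markers 7 of 12 rose (8 adjusted over the list alone; adjusted p = 0.00118), with Pi16 at 1.102, Dpt at 0.89, Dclk1 at 0.80 and Gsn at 0.79 (-0.10 and not past with the length offset). All 3 macrophage markers measured rose, counted either way (adjusted p = 0.00516): Spi1 (2.55; 0.17 and not past with the uncalled length filled), C1qb (2.01) and Cd68 (0.54); over the gene body, where 7 are measured, the list did not pass. Of the IL-6, STAT and inflammation genes 9 of 14 rose and 1 fell, counted either way (adjusted p = 0.0108), with Tnfrsf1a at 1.32, Osmr at 0.76, Nfkb1 at 0.30 (-0.0015 filled, -0.70 with the length offset) and Lifr at -0.44. With the length offset 2 rose and 2 fell, and the median's distance from all promoters went from 0.28 to 0.08. Within the classes of nuclei named below, 0 of 90 regions over the progenitor markers rose or fell in progenitor-like nuclei. In macrophage-like nuclei 1 of 13 regions over their markers rose and 0 fell, and in endothelial-like nuclei 0 of 15 changed. The rises of these markers over all nuclei therefore cannot be told apart from larger shares of such nuclei. The medians of the embryonic, matrix, progenitor and macrophage lists stayed above 0 and above all promoters under every scaling, but with the offset for called length 5 matrix genes rose and 1 fell (median 0.52 to 0.02) and 2 progenitor markers (0.54 to 0.04), 2 embryonic genes and 2 macrophage markers rose.

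The other lists did not pass camera in the main fit. Of the ubiquitin ligase and autophagy genes, the atrophy list, 4 of 26 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.742; 10 and 2 with library size alone, 1 and 9 with the length offset): Gabarapl1 (0.55) and Tnfrsf12a (0.34) rose while Asb2 fell by 1.95. Of the myogenic regulators 2 of 18 rose, Myog and Runx1, and 3 fell, among them Myod1 (-0.33; adjusted p = 0.591). Rises and falls numbered 7 and 3 of 24 TGF-beta and BMP genes, 5 and 3 of 14 ETS factors (6 and 3 adjusted over the list alone), 2 and 4 of 16 AP-1 and immediate early genes, 0 and 4 of 17 circadian clock genes, and 3 and 0 of 13 proliferation genes. Among cell type markers they numbered 4 and 0 of 5 for endothelial cells (1 and 0 with the uncalled length filled, 0 and 0 with the length offset), 2 and 0 of 4 for tenocytes, 2 and 3 of 9 for mural cells (2 and 4 adjusted over the list alone), 0 and 1 of 6 for satellite cells, 3 and 1 of 5 for Schwann cells, 1 and 0 of 4 for adipocytes, 1 and 1 of 4 at the myotendinous and 3 and 2 of 8 at the neuromuscular junction (3 and 4 adjusted over the list alone). Where no second count is given, adjusting over the list alone gave the same. Most of these counts shift towards rises with library size alone and towards falls with the length offset. Too few lymphocyte markers had a shared promoter region for a test. The median and the test also differed in sign for the myogenic and neuromuscular junction lists. With the estimated correlation 9 lists had an unadjusted p under 0.05 by camera (smallest adjusted p 0.0690), and fry, which asks whether a list's genes move on balance in 1 direction, passed 19.

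**Figure D2:**
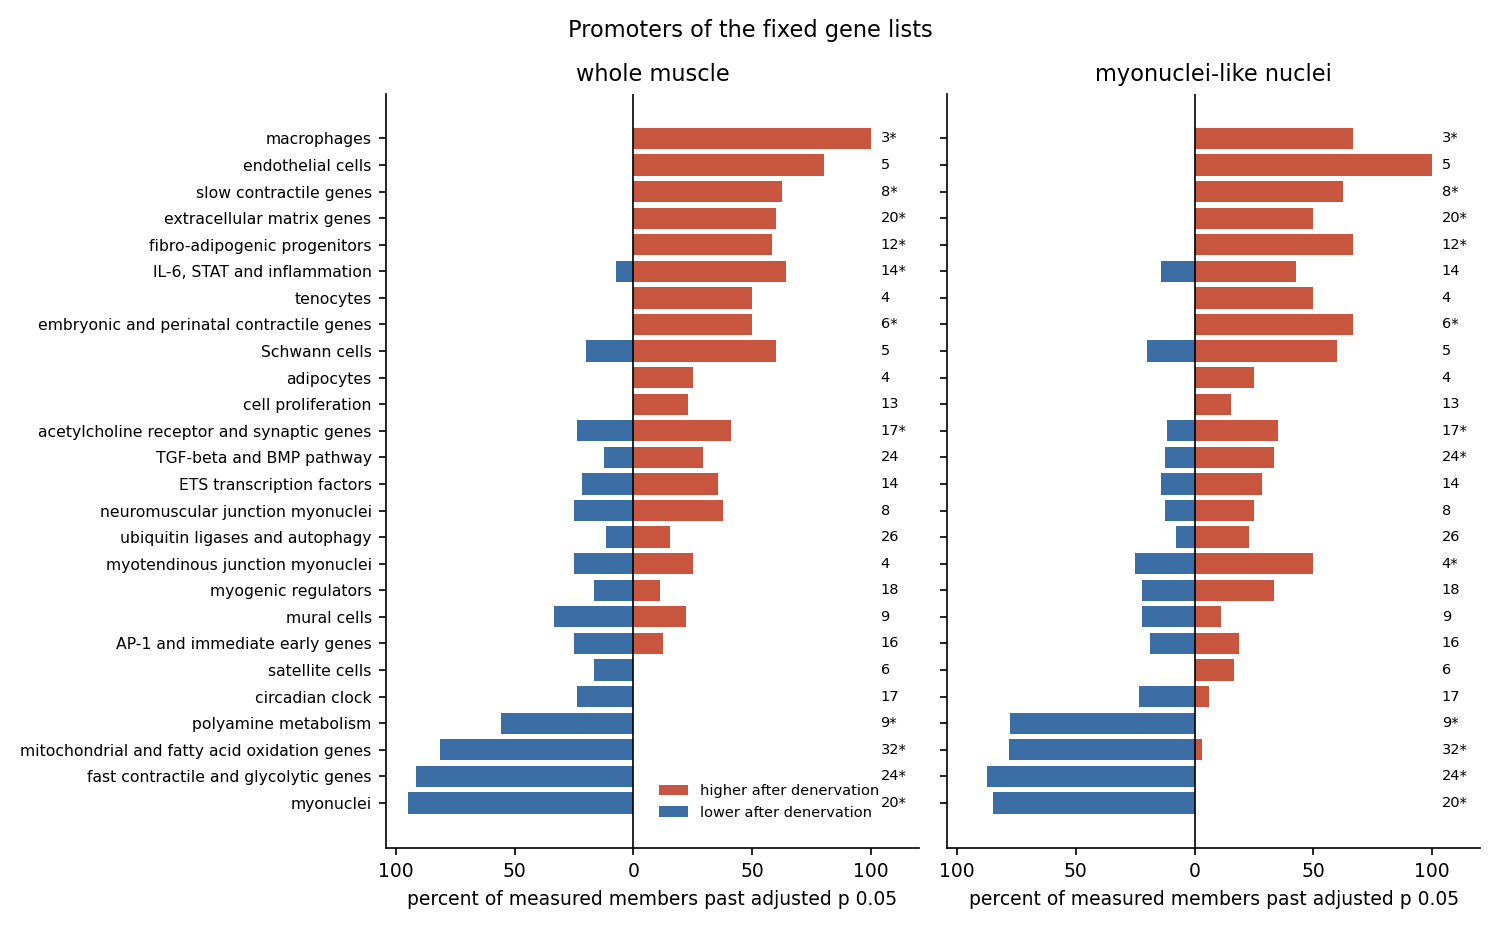
Percent of the measured members of each gene list whose promoters passed an adjusted p of 0.05, higher or lower in denervated muscle, for all nuclei and for myonuclei-like nuclei; the number beside each list is its measured members and a star marks a camera adjusted p under 0.05. The bars of the fast contractile, mitochondrial and myonuclei lists lie almost wholly on the lower side, under every scaling tried; the slow contractile list of all nuclei no longer stands above all promoters (-0.0032) with an offset for called length.

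Over all shared regions of whole muscle the comparison asks where in the genome accessibility changed. Gains lay mostly away from gene starts, and the widest regions mostly lost counts. Regions that gained were rich in AP-1 and RUNX sequence motifs, and regions that lost were rich in MEF2 motifs. Of 58958 regions 11758 rose and 10707 fell (edgeR's quasi-likelihood test, adjusted p under 0.05), and in 32470 (55.1%, chance 10%) the groups did not overlap. Library size alone gave 15750 rises and 7787 falls, and the length offset 4366 and 18394 (medians of all regions 0.19 and -0.20). The largest rises were at chromosome 18, 24094973 to 24095711, between genes and nearest to Ino80c (0.01 ± 0.02 to 6.09 ± 0.18 CPM), and inside Inpp4a, Fggy, Hk1 and Susd1. With the uncalled length filled these were 0.85, 0.49, 0.94, 1.74 and 1.65 in log2, and Inpp4a did not pass with the length offset (0.77, adjusted p = 0.0944). The Ino80c region had 5.33 bp called on average in normal and 695 bp in denervated libraries. The Hk1 region (chromosome 10, 62320072 to 62321218) went from 0.37 ± 0.31 to 17.3 ± 1.56 (log2 5.58 ± 0.55). The largest fall, -6.85 ± 0.78, was between genes nearest to Amd1 (chromosome 10, 40279134 to 40287576), from 118 ± 24.0 to 1.04 ± 1.06 CPM (-1.63 filled; adjusted p = 0.000707). The next were in Gramd4 (-5.13, -0.70 filled), near Rbm38 (-4.87, -0.21 filled and no longer past), near Klhl38 (-4.81, -0.50 filled) and in Vdac2 (-4.81, -1.28 filled).

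Of the 213 shared regions wider than 20 kb, 150 fell and 9 rose (median log2 -0.94), against 2972 falls and 3754 rises of 24844 regions up to 1 kb. Promoters made up 13.3% of the higher, 22.4% of the lower and 24.5% of the uncalled regions (odds ratios against the last of 0.472 and 0.890; Fisher's exact test p = 5.36e-157 and 8.52e-06). Within 250 bp of region centres, in strata of GC content, the AP-1 motif was more frequent in higher regions than in uncalled ones (odds ratio 2.11, 95% interval 2.00 to 2.23) and less frequent in lower ones (0.710, 0.657 to 0.766). The RUNX motif had odds ratios of 1.48 (1.39 to 1.58) and 0.840, and the E-box CAGCTG, which myogenic factors bind, 1.22 and 0.930. MEF2 was more frequent in lower regions (1.77, 1.64 to 1.91), as were the glucocorticoid response element (1.42; 1.25 and not past in a window of 100 bp) and the ERR motif (1.41). The PU.1 motif was more frequent in higher regions of whole muscle (1.23, 1.11 to 1.37), a call lost in a window of 100 bp (1.13, 0.953 to 1.34), and did not pass in myonuclei-like nuclei (1.08, 0.971 to 1.20; 0.902 in the smaller window). CTCF motifs were rarer in both (0.179 and 0.381). Neighbouring regions are not independent, so these intervals are narrower than replicates would give.

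**Figure D3:**
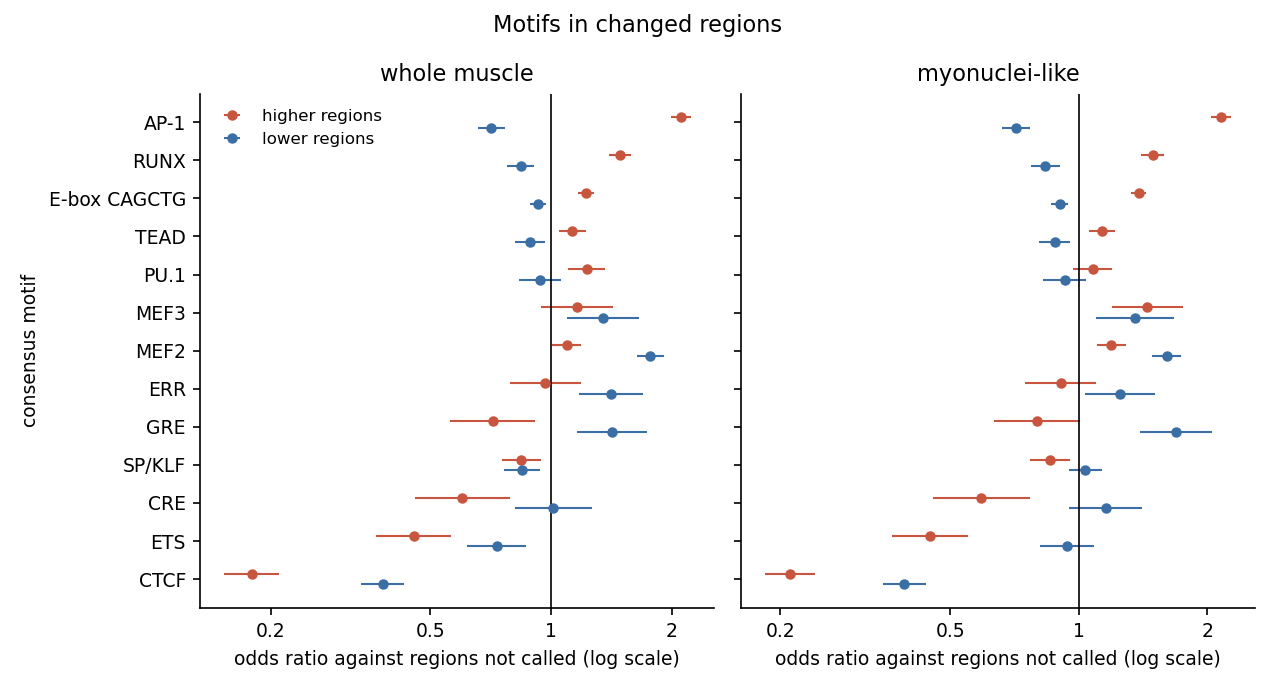
Odds ratios with 95% intervals for sequence motifs in regions that rose or fell, against tested regions that did neither, for all nuclei and myonuclei-like nuclei. AP-1 lies at 2.11 and 2.16 in regions that rose, MEF2 at 1.77 and 1.61 in regions that fell, and CTCF below 1 in both.

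Nuclei were then clustered and clusters named from fixed marker genes, to ask what changed within the muscle nuclei themselves. The changes of whole muscle were found again in the 15019 nuclei that resembled myonuclei. In the main fit most fast, mitochondrial and polyamine genes of the lists fell. The receptor subunits Chrna1 and Chrnd and several genes of the slow and embryonic contractile lists rose. Polyamine falls numbered 7 of 9 there, but 3 with library size alone and 3 with the length offset. Of 13563 promoters 2885 rose and 2620 fell (edgeR's quasi-likelihood test, adjusted p under 0.05), with the groups apart in 7324 (54.0%, chance 10%). Library size alone gave 5306 rises and 1028 falls, and the length offset 1182 and 3955 (medians 0.19 and -0.17). The largest rises were at Eppk1 (6.85), Mymk, the muscle fusion factor myomaker (5.47), Slc6a15, Ankrd1, Scd4, Gng4, Aqp1 and Enpp3 (4.37). Mymk (chromosome 2, 27061636 to 27072179) went from 0.91 ± 0.28 to 39.9 ± 14.8 CPM (SD, n = 3; adjusted p = 4.34e-06), and 2.23 of its log2 change remained with an offset for called length. The largest falls were at Slc2a2 (-3.43), Mylk4, Cmtm1, Smox, Smco1, Shc2, Fam131b and Rims4 (-2.71). Chrna1 rose by 4.27 ± 0.28 (5.91 ± 3.14 to 114 ± 18.2), Runx1 by 1.62 ± 0.08 and Myog by 1.51 ± 0.12, the last at 0.0063 with the length offset. Myh4 fell by 2.17 ± 0.19 (2815 ± 321 to 626 ± 131) and Myh1 by 1.22 (-0.01 with the length offset). Trim63 (-0.61, adjusted p = 0.0774) and Fbxo32 (0.20, adjusted p = 0.438) did not pass.

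With an estimated correlation none of the following lists passed camera. Within these nuclei 21 of 24 fast contractile genes fell (22 adjusted over the list alone; camera adjusted p = 6.85e-17), 25 of 32 mitochondrial genes fell and 1 rose (26 and 1; adjusted p = 6.12e-09), and 17 of 20 myonuclei markers (18; adjusted p = 2.99e-13) and 7 of 9 polyamine genes fell (7; adjusted p = 0.000336). Mybpc2 (-2.39), Gpd1 (-1.29), Perm1 (-1.71), Slc25a4 (-1.51) and Amd1 (-1.87) led. The polyamine falls dropped to 3 of 9 with library size alone and to 3 with the length offset. Mitochondrial falls dropped to 17 and 20 of 32. Relative to all promoters the polyamine median stayed lower, at -0.33 with library size alone and -0.095 with the length offset. The mitochondrial median stood at -0.43 and -0.16. Higher were 6 of 17 receptor and synaptic genes, with 2 lower (adjusted p = 2.21e-06), 4 of 6 embryonic (adjusted p = 1.81e-07), 5 of 8 slow (6 adjusted over the list alone; adjusted p = 0.000371) and 8 of 24 TGF-beta and BMP genes, with 3 lower (adjusted p = 0.00577). Chrnd (2.94), Ncam1 (2.45), Myom3 (2.72), Myoz2 (2.34) and Tnnt1 (2.00) rose, as did Id1 (1.74), Tgfb1 (1.66), Ltbp1 (1.53) and Id2 (1.07). The TGF-beta, macrophage and myotendinous calls were lost with counts over the gene body. Higher too were 10 of 20 matrix genes (14, with 1 lower, adjusted over the list alone; 6, with 4 lower, with the length offset; adjusted p = 0.00357), 8 of 12 progenitor markers (adjusted p = 3.56e-05), 2 of 3 macrophage markers (adjusted p = 0.0236) and 2 of 4 myotendinous genes with 1 lower (adjusted p = 0.0352); counts from other nuclei in the same droplets were not removed.

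Of the lists that did not pass in these nuclei, 6 of 26 atrophy genes rose and 2 fell (6 and 1 adjusted over the list alone; adjusted p = 0.795; 11 and 1 with library size alone, 3 and 8 with the length offset), with Gabarapl1 at 0.96 and Asb2 at -1.73, and 6 of 18 myogenic regulators rose and 4 fell (adjusted p = 0.165; 8 and 0 with library size alone, 1 and 4 with the length offset). Rises and falls numbered 6 and 2 of 14 IL-6 and inflammation genes, 4 and 2 of 14 ETS, 3 and 3 of 16 AP-1, 1 and 4 of 17 clock and 2 and 0 of 13 proliferation genes. They numbered 5 and 0 of 5 endothelial, 2 and 0 of 4 tenocyte, 1 and 2 of 9 mural, 1 and 0 of 6 satellite cell, 3 and 1 of 5 Schwann cell, 1 and 0 of 4 adipocyte and 2 and 1 of 8 neuromuscular junction markers. Where no second count is given, adjusting over the list alone gave the same. Most of these counts too shift with the scaling. The median and the test differed in sign for the proliferation list. With an estimated correlation camera again passed 0 lists (8 at an unadjusted p under 0.05; smallest adjusted p 0.0704), and fry passed 23.

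Regions tested within myonuclei-like nuclei address the same question away from promoters. Here too the widest regions mostly fell, and AP-1, RUNX and E-box motifs marked the gains. Of 58762 regions 13740 rose and 12124 fell (edgeR's quasi-likelihood test, adjusted p under 0.05), with the groups apart in 33959 (57.8%, chance 10%). Library size alone gave 16981 rises and 7857 falls, the length offset 9475 and 17188 (medians 0.22 and -0.20), and components centred per library 4523 and 1004. Rises were largest at the region near Ino80c (0.0070 ± 0.01 to 8.04 ± 0.25 CPM), in Susd1 (0.22 ± 0.20 to 62.0 ± 9.04), near Tubb2a, near Zfp438 and in Zdhhc14. Falls were largest near Amd1 (161 ± 31.1 to 1.43 ± 1.56, log2 -6.69 ± 0.71), in Gramd4 (-5.06), Celf2 (-5.00) and Nfkbiz (-4.93), and in Mn1 (-4.87; past the threshold except without denervated 2). With the length offset these rises were 3.08 to 4.64 and these falls -0.97 to -2.75. Of the regions wider than 20 kb 148 fell and 10 rose. Promoters were 12.2% of the higher, 29.3% of the lower and 23.3% of the uncalled regions (odds ratios 0.457 and 1.36; Fisher's exact test p = 1.63e-176 and 8.57e-38). In higher regions the odds ratio was 2.16 for AP-1, 1.49 for RUNX and 1.38 for the E-box CAGCTG, and in lower regions it was 1.69 for the glucocorticoid response element, 1.61 for MEF2 and 1.25 for ERR; MEF2 was also more frequent in higher regions (1.19, adjusted p = 3.69e-05).

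The share of each class among nuclei with at least 1000 counts was compared to ask whether the cell composition changed. Macrophage-like and fibro-adipogenic progenitor-like nuclei made up larger shares of every denervated library than of any normal one, and myonuclei-like nuclei smaller shares. Macrophage-like nuclei were 9.47 ± 1.90% after denervation and 3.93 ± 0.84% in normal muscle (SD, n = 3), progenitor-like nuclei 29.8 ± 0.99% and 23.3 ± 2.40%, and myonuclei-like nuclei 38.1 ± 6.82% and 52.7 ± 2.67%. Each gave an exact permutation p of 0.1 (0.333 adjusted over 10 classes), the smallest possible, so none passed. With components centred per library, which changed which clusters could be named, the macrophage-like difference went from 5.53 to 2.94 points and the progenitor-like from 6.48 to 3.36. The myonuclei-like difference turned from -14.6 to 38.6 points. The myonuclei share is not read as a change, since 33 of 50 regions over its own markers fell within the class and 2 rose, and of the 1802 nuclei in 1 cluster that could not be named 708, 1034 and 57 came from the denervated and 1, 2 and 0 from the normal libraries. Mymk, Ankrd1 and Igfn1 are among the leading genes of that cluster. Of its nuclei 38.5% resembled simulated doublets, over the limit of 30%, and their median depth was 2.78 times that of their library. Its best marker share was 0.286. Whether it holds a state of muscle nuclei or doublets was not tested. The remaining shares were 2.50 ± 0.77% and 2.04 ± 0.48% for endothelial-like, 1.68 ± 0.54% and 1.86 ± 0.37% for satellite cell-like, 1.75 ± 0.07% and 1.52 ± 0.38% for tenocyte-like, 0.91 ± 0.46% and 1.32 ± 0.16% for mural-like, 0.69 ± 0.13% and 0.93 ± 0.85% for adipocyte-like and 14.96 ± 10.0% and 10.3 ± 1.51% for unnamed nuclei. Of 488 lymphocyte-like nuclei 443 came from normal 2, where they were 6.14% (95% Clopper-Pearson interval 5.59 to 6.72%).

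**Figure D4:**
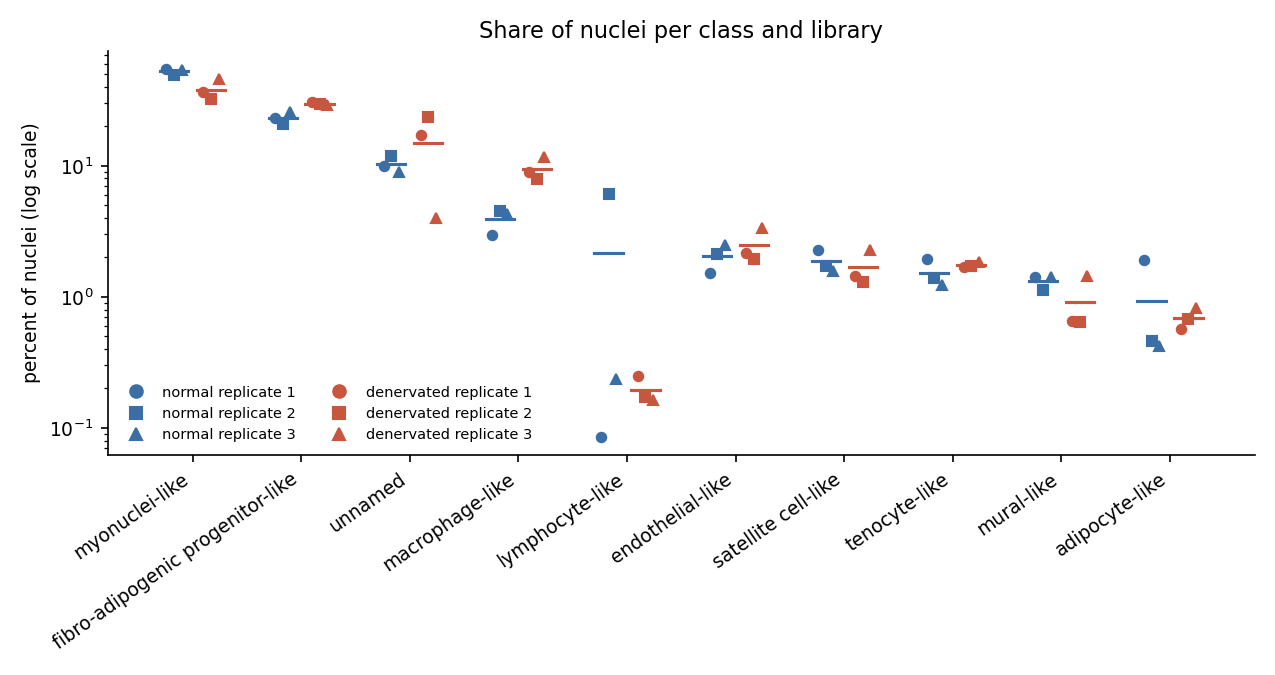
Percent of nuclei in each class in the 3 normal and 3 denervated libraries, on a logarithmic axis; each point is a library. Macrophage-like nuclei lie between 7.92 and 11.6% after denervation and between 2.97 and 4.54% in normal muscle.

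The other classes with at least 50 nuclei in every library were tested for changed regions, to ask which non-muscle nuclei responded. Calls in macrophage-like nuclei were mostly gains and those in satellite cell-like and tenocyte-like nuclei mostly losses. The muscle marker signal in these classes moved the same way, from 15.005 to 22.4% of the myonuclear level in macrophage-like and from 27.2 to 21.9% and 31.2 to 19.5% in the others. Of the satellite cell-like falls 208 of 258 and of the tenocyte-like falls 225 of 236 were within 3 times what that muscle signal would give. Of the rises 268 of 314 in macrophage-like, 123 of 135 in satellite cell-like and 57 of 64 in tenocyte-like nuclei were beyond it or went the other way. In progenitor-like nuclei 159 of 300 rises were, and 141 were within it. That signal was taken from the myonuclei-like nuclei, without the unnamed cluster led by Mymk and Ankrd1. Regions at the muscle genes Mylk4 and Myom2 were among the largest falls in some of these classes. By edgeR's quasi-likelihood test (adjusted p under 0.05) 314 regions rose and 75 fell in macrophage-like, 300 and 153 in progenitor-like, 135 and 258 in satellite cell-like, 64 and 236 in tenocyte-like and 21 and 31 in endothelial-like nuclei. These totals moved with single libraries: leaving 1 out gave 111 (without denervated 1) to 561 (without normal 2) for macrophage-like, 2 (without denervated 1 or 2) to 1433 (without normal 3) for progenitor-like, 123 (normal 2) to 811 (normal 3) for satellite cell-like, 113 (normal 2) to 707 (normal 3) for tenocyte-like and 31 (denervated 2) to 86 (normal 3) for endothelial-like nuclei. No value with the uncalled length filled or offset exists for these classes, so counts of 0 can reflect uncalled length. In macrophage-like nuclei regions inside Ulk4 (211 bp called in normal, 2834 in denervated libraries) and Ube2h (168 and 1484 bp) went from no counts to 10.8 ± 1.55 and 10.2 ± 1.20 CPM, and regions in Optn (-4.35) and Mylk4 (-3.97) fell. In satellite cell-like nuclei the Eppk1 promoter (165 and 3257 bp called) went from no counts to 40.2 ± 9.91, and a Mylk4 region fell from 84.1 ± 27.2 to 0.58 ± 1.01. In tenocyte-like nuclei regions in Ppp1r12c (4.88) and Mtor (4.62) rose, and that near Mn1 (-5.23) fell. In progenitor-like nuclei the Fggy region rose by 4.97 ± 0.38 and that near Amd1 fell by 5.65 ± 0.40. Without denervated 1, and again without denervated 2, 0 regions rose in this class, so the Fggy call was lost there. In endothelial-like nuclei a region in Runx1 rose (4.72; 4.62 and not past the threshold without denervated 3), and those of Myom2 (-3.83) and the Mylk4 promoter (-3.44) fell. Most called regions had also been called in the same direction in myonuclei-like nuclei, for example 219 of 236 tenocyte-like falls, where 64.7 would be shared if the calls were independent.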

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

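The pooled tests by direction and the counts over other splits of the libraries were chosen only after the results were seen; the 5 tests per class were planned before them, but the demand that a bound be passed by more than counting error was added after their values were seen, and moved endothelial-like nuclei from against to undecided.

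The change on denervation differed between classes of nuclei, which was tested directly as an interaction of class and treatment by edgeR's quasi-likelihood test (adjusted p under 0.05). Against myonuclei-like nuclei 15126 regions differed in fibro-adipogenic progenitor-like, 4102 in macrophage-like, 2536 in satellite cell-like, 1392 in tenocyte-like and 1019 in endothelial-like nuclei. Nuclei of a library enter both sides of each test. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split was the 1 of 10 with as many, and the highest of the others gave 0, 0, 38, 3 and 5 such regions in that order. Those splits mix normal and denervated libraries on each side, which adds to the spread and lowers the calls by itself.

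Regions called in the other classes were mostly ones called the same way in myonuclei-like nuclei, for example 271 of 298 progenitor-like rises (69.9 if independent) and 73 of 75 macrophage-like falls (17.8 if independent). Muscle DNA in the droplets of other nuclei might give this: regions of the myonuclei markers stood, in normal and then denervated libraries, at 15.005 and 22.4% of the myonuclear level in macrophage-like, 11.8 and 18.1% in progenitor-like, 15.2 and 20.0% in endothelial-like, 27.2 and 21.9% in satellite cell-like and 31.2 and 19.5% in tenocyte-like nuclei. If that were the whole cause, a change should be near that of the muscle level times the share of its group, and over 50% of regions beyond 3 times it, or the other way, was set as the bound against it and under 10% as the bound for it. The percent beyond was 75.8 in macrophage-like nuclei, which argues against DNA of the myonuclei-like nuclei as the whole cause there. It was 53.8 in endothelial-like (28 of 52, 95% interval 39.5 to 67.8), 46.6 in progenitor-like, 44.0 in satellite cell-like and 22.7 in tenocyte-like nuclei. In these 4 classes muscle DNA cannot be told apart from a response of the class, since neither bound was passed by more than counting error. Taking the 5 classes together, 74.7% of 834 rises (159 of 300 in progenitor-like nuclei) and 20.2% of 753 falls lay beyond. DNA of the myonuclei-like nuclei is thus argued against for the rises as a set. It cannot be told apart for the falls, which it may explain. The muscle level came from the myonuclei-like nuclei alone. The unnamed cluster of 1802 nuclei has Eppk1, Ankrd1 and Mymk among its leading genes, but 38.5% of its nuclei resembled simulated doublets. DNA from that cluster was not tested, so it stays open for the rises, whatever nuclei the cluster holds. An own response of these nuclei to denervation stays open too, as untested.

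Other splits of the 6 libraries called at most 1 region in endothelial-like (real 52) and tenocyte-like (real 300) nuclei and 0 in progenitor-like (453), macrophage-like (389) and satellite cell-like (393) nuclei by edgeR; at an unadjusted p under 0.05 their highest counts were 812, 1281, 3783, 1076 and 1481 in that order, against 1151, 2131, 8613, 2931 and 2585 in the real split. With 10 splits no share under 0.05 can be reached, and the mixed groups of the other splits lower their calls by themselves.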

How the results depend on the processing

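Added after seeing the data were the fill of uncalled length, library size only, the earlier naming rule, the batch term and replicates 1 and 2 alone; the cause of a difference below was not tested unless its construction shows it. Of 1952 values under alternatives for all named whole-muscle promoters 1779 kept direction and side of the threshold, 91 lost and 25 gained the call, and 57 reversed (27 of these for promoters past the threshold); of 1837 within myonuclei-like nuclei 1725 kept both, 55 lost and 27 gained it, and 30 reversed (10 past); of 719 for named regions 662 kept both and 57 lost the call, mostly in the smaller classes; of 196 for motifs 166 kept both, 15 lost and 3 gained it, and 12 reversed, none of them past the threshold (of those the report prints PU.1 in myonuclei-like gains, 0.902). Reversals are named below only for a subset of promoters, chosen after many had been seen; it holds every promoter value the report prints that reverses, and the others are values it does not print. Differences in peaks, covered length, nuclei and counts per nucleus kept their direction in all 30 values, though that in median counts per nucleus (4334) nearly vanished without denervated 3.

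Whole-muscle regions past the threshold (22465) numbered 45678 among regions in at least 3 libraries, where more regions are tested (43818 with the uncalled length filled), 13380 with 0.5 of the merged length called and 10753 with peaks over 5 CPM, where fewer are; leaving out a library gave 14943 (without denervated 2; 15385 without denervated 1) to 22440. Promoters (4978) ranged from 3130 (without denervated 2; 3177 without denervated 1) to 5103. Myonuclei-like regions (25864) numbered 48547 in at least 3 libraries, 14908 with 0.5 of the length, 12002 with peaks over 5 CPM, 16664 under the earlier naming rule and 5527 with components centred per library. Leaving out a library took the endothelial-like count (52) to 31 (denervated 2) and 86 (normal 3), the progenitor-like (453) to 87, 196 and 1433 (normal 1, 2 and 3) and 2, 2 and 57 (denervated 1, 2 and 3), the macrophage-like (389) to between 111 and 561 (denervated 1, 111; denervated 2, 112; denervated 3, 208), the satellite cell-like (393) to 162, 123 and 811 (normal 1, 2 and 3), 200 and 171 (denervated 1 and 3), and the tenocyte-like (300) to 123, 113 and 707 (normal) and 132, 159 and 155 (denervated). Without the low count filter they were 112 endothelial-like, 1176 macrophage-like, 852 satellite cell-like and 759 tenocyte-like. The normal 3 and denervated 3 libraries deviate together and no label gives a batch: replicates 1 and 2 alone gave 26471, 5734, 26935 and 5869 in the 4 large comparisons and a batch term 26951, 6219, 29089 and 6445; replicates 1 and 2 alone also gave 23 endothelial-like, 2719 progenitor-like, 245 macrophage-like and 558 tenocyte-like regions; replicate 3 alone is 1 against 1, too few to test. With the replicate block progenitor-like regions numbered 1421 and whole-muscle regions 23620, though the numbers do not pair the libraries (correlations of equal numbers 0.078, 0.081 and 0.247).

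With the length offset, which moves the median of all promoters to -0.17, so that values between it and 0 are no lower than promoters at large, these whole-muscle promoters reversed: Myog -0.30, Runx1 -0.25, Chrnd -0.13, Gsn -0.10, Nfkb1 -0.70 (-0.0015 filled), Amd1 0.0024, Tnnt1 -0.17, Myoz2 -0.0245, Tpm3 -0.17 and Traf6 -0.22; within myonuclei-like nuclei Tpm3 -0.0297 and Psmd11 -0.25 did. Gng4 reversed with the fill (-0.0394), and a result never called (promoters, whole muscle: Fbxo32) with library size only (0.0832) and over the leave-outs (-0.219 to 0.0873). Lists past camera fell to 0 and 0 (whole muscle, myonuclei-like) with an estimated correlation and rose to 19 and 23 by fry; calls lost with gene activity were slow and macrophage (whole muscle) and TGF-beta, macrophage and myotendinous (myonuclei-like), and slow was lost filled (whole muscle, adjusted p = 0.0630). Besides fry, calls gained in whole muscle were TGF-beta filled (adjusted p = 0.0170), myotendinous with the replicate block (0.000335) and replicates 1 and 2 alone (0.0269), and tenocytes (0.0483) and clock (0.0487) with the latter; in myonuclei-like nuclei the neuromuscular junction list was gained with the replicate block (0.0169). Uncalled lists reversed: mural with gene activity (0.17 and 0.17) and replicates 1 and 2 (0.15), satellite filled (-0.0592), while for atrophy in myonuclei-like nuclei with gene activity only the direction of the test turned (median 0.0298, as before above 0).

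With components centred per library, which changed which clusters could be named, the differences in share were 2.94 points for macrophage-like (5.53 before), 3.36 for progenitor-like (6.48 before), 38.6 for myonuclei-like, 0.03002 for satellite cell-like and -43.7 for unnamed nuclei; without doublet-like nuclei the satellite share differed by 0.0592. Under the earlier naming rule they were -33.2 for myonuclei-like and 27.5 for unnamed nuclei, and macrophage-like and lymphocyte-like clusters had no name and so no value. Over the leave-outs differences ranged from -0.50 to 0.25 for adipocyte-like, -0.488 to 0.0276 for satellite cell-like and -2.99 to 0.0346 (without normal 2) for lymphocyte-like nuclei. By edgeR on nuclei per class the macrophage-like rise passed (log2 1.27, adjusted p = 0.0333), where the permutation test cannot. Regions called only after denervation numbered 7461 with peaks over 5 CPM. Depth limits the classes: a library held as few as 52 tenocyte-like nuclei.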

Other observations

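Chosen only after the result was seen were the tests of called length and of fewer muscle nuclei for the wide regions and all counts over other splits; the tests of regions called only after denervation and of the abundance trend were planned before.

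The 20706 regions called only in the denervated libraries might arise from more counts per library, or from more nuclei of other classes. In all 3 denervated libraries 71.5% of them lay above the 10th percentile of the called regions of each normal library. That passed the bound of 50% set beforehand against depth at the calling limit. But the regions were picked for being called in these libraries, and most called regions lie above such a percentile by construction. The share therefore cannot tell depth apart from newly open sites. In all 3 libraries 70.1% had higher CPM in myonuclei-like than in all other nuclei and 21.4% were higher in the others, which argues against other classes as the source of most of them. A response of muscle nuclei to denervation is a candidate explanation that these tests leave open, without proving it.

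The 213 regions wider than 20 kb, of which 150 fell, could have lost called length, could reflect fewer muscle nuclei in the libraries, or could follow a trend with abundance. With the uncalled length filled 140 of the 150 stayed lower, and the median of the 213 went from -0.94 to -0.50. The fill stood at 388, 405 and 365 counts per kb in the normal and 352, 327 and 379 in the denervated libraries. It can thus lower filled regions by itself, so the kept calls argue only weakly against called length as the whole cause. Within myonuclei-like nuclei alone 69.5% of the 213 were lower, which argues against fewer muscle nuclei as the whole cause. With loess offsets against abundance 105 of 150 stayed lower, short of the bound set beforehand, so the abundance trend cannot be told apart from a loss specific to such regions.

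For results across all libraries the 10 splits are too few for a share under 0.05. Every other split also mixes normal and denervated libraries on each side. The group difference then adds to the spread within a side and lowers the calls by itself, so low counts in these splits say little. The real split gave 22465 regions and 4978 promoters in whole muscle and 25864 and 5505 in myonuclei-like nuclei, and each of the other 9 splits gave 0 by edgeR (at an unadjusted p under 0.05 at most 1910, 603, 1627 and 463, against 28354, 6445, 30513 and 6811). Regions called in all libraries of 1 group alone numbered 23454, and 872 in the highest other split. Camera with its preset correlation passed 11 lists in whole muscle and 12 in myonuclei-like nuclei, and up to 9 in other splits for each, so the number of lists it passes says little by itself.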
